A study of Danio rerio with 5 samples.

How the data were processed

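Total RNA of young adult zebrafish was hybridised to Affymetrix zebrafish 3' expression arrays, 1 array for each of 5 conditions: DMSO, benzene, toluene, formaldehyde and the BTF mix of these 3 compounds. Per the labels' protocols, the compounds were prepared in DMSO, fish were exposed for 24 h without food, RNA was extracted with a column kit and biotin-labelled cRNA was made from it. Samples were grouped by the treatment given in the labels. The labels give a single entry for the sex of all fish that names no male or female group, and the tissue, the number of fish per array and the doses are not given in the sources used here.

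The deposited table of the authors holds log2 values, 1 per probe set and array. Per the submitters' processing notes, RMA, MAS5 and Affymetrix Expression Console 1.1 were used; the role of MAS5 is not given in the sources used here. The values have the features of RMA, which corrects the background, quantile normalizes probes between arrays and summarises the probes of a set by median polish: they lay between 3.15 and 15.04 on all arrays, and 21.9% of probe sets had identical values on at least 2 arrays. The log base was taken from that range. Quantile normalization makes the total signal of the arrays alike, so where a large class of transcripts is missing from 1 array, the others are raised on it. RMA values near the top of the range are compressed, so differences of very abundant transcripts are understated.

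Control probe sets, 115 in number, were left out. Of the remaining 15502, 10795 were paired with exactly 1 gene symbol in the platform annotation, 135 with several and 4572 with none. Symbols were updated through Entrez identifiers with NCBI RefSeq's gene table (assembly GRCz12tu), where 10711 matched. No coordinates were used other than the order of genes. Probe sets entered the counts where their highest value over the 5 arrays reached the median of all values, 7.02, which 9716 did. For gene lists, each gene was represented by the probe set with the highest mean, which gave 6682 genes. Among 864 genes with at least 2 probe sets, the median gap between the differences of a gene's probe sets was 0.18 for benzene, 0.18 for toluene, 0.19 for formaldehyde and 0.55 for the mix.

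With 1 array per group, no test, p-value or replicate spread exists. Each exposed array was set against the DMSO array as a difference of log2 values, and differences of at least 1 (2-fold) were counted. A total of 35 gene lists for functions and cell types was fixed before the data were examined, and 34 had at least 5 measured genes. For each, the median difference was given as a percentile among 10000 random lists of the same size, matched on mean level in 20 bins (seed 20240). Some genes are on several lists. Several listed tissues share genes with others, so the lists are not independent of each other.

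Named genes followed a rule fixed at the same time: per comparison, the 12 with the largest increase and the 12 with the largest decrease among genes past the filter that have a usual name, and up to 4 members with the largest difference in each list that stood apart or had at least 3 members 2-fold apart. For the comparison of toluene with benzene only the first part was used. The probe set of highest mean stands for the gene, and other probe sets that disagreed are given for the genes with the largest differences. The report prints most of the genes so chosen and leaves out some list members. It adds a few members of the foreign compound, aldehyde and fasting lists from outside the rule. A value whose second decimal is 0 is in places printed with 3 decimals.

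All comparisons share the DMSO array, so correlations between them were set beside those of 100 simulated tables of unchanged arrays. Their noise was drawn from a normal distribution, the same for the mix as for the other arrays. Its size was taken from the difference of the toluene and benzene arrays at each level, which includes any true difference between these. Pairs of differences with no array in common were also correlated.

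The steps were tested on a simulated table for the comparison of benzene with DMSO, with 8384 probe sets past the filter. Of 67 probe sets changed by 1.5, 98.5% were counted, of 66 changed by 3 all 66, and of 67 changed by 0.8, 26.9%. Of 8151 unchanged ones 13 were counted, or 0.16%. Between the real benzene and toluene arrays, 1.77% of probe sets were at least 2-fold apart. The simulated noise, drawn from a normal distribution, thus held fewer large differences than that pair. The 13 is therefore no estimate of false counts in these data. The noise of that table is that between 2 arrays of different exposures and not that between replicates. Among 5984 simulated genes a list of 31 shifted by 0.6 had a median of 0.54 and stood apart, as did 1 of the other 127 combinations of list and exposure.

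Alternatives tried were quantile and cyclic loess normalization of the deposited values, no level filter or one at the 75th percentile, thresholds of 1.5-fold and 3-fold, 1 probe set per gene, the mean of a gene's probe sets, other reference arrays, Spearman correlation, and leaving out egg-related lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for loess.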

Results

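Gene expression was measured in young adult zebrafish of the AB wild-type line after a 24 h exposure without food. Fish were kept in the vehicle DMSO, or in formaldehyde, toluene or benzene, or in a mixture of these 3 compounds, called the BTF mix here. Benzene and toluene are aromatic solvents, and formaldehyde is a reactive aldehyde; all 3 are common pollutants of indoor air. Each of the 5 conditions had 1 Affymetrix array, so no difference below has a replicate check and no test was run. The tissue, the number of fish behind each array and the doses are not given in the sources used here. The deposited table is on a log2 scale; 115 control probe sets stayed out of the comparisons. The array medians of the other 15502 probe sets lay between 6.98 and 7.06. Of these, 9716 reached the median of all values, 7.02, on at least 1 array and entered the counts of differences, and they covered 6682 genes paired with exactly 1 symbol. The number of arrays limits the precision of every value.

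The DMSO, benzene, toluene and formaldehyde arrays were close to each other, and the BTF mix array stood far from all of them. Across probe sets, the correlations among the first 4 arrays ran from 0.979 to 0.992. The BTF mix array had correlations of 0.713 with DMSO, 0.739 with benzene, 0.737 with toluene and 0.692 with formaldehyde. Transcripts of oocytes were among the most abundant on the first 4 arrays: zar1, a maternal factor needed at the egg-to-embryo transition, had a level of 13.74 with DMSO, 13.62 with benzene, 13.67 with toluene and 13.61 with formaldehyde, and 6.14 with the mix. The yolk precursor vtg2 had levels of 14.08, 14.21, 14.09 and 12.76 on the first 4 arrays in the same order, and 5.96 with the mix.

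**Figure D1:**
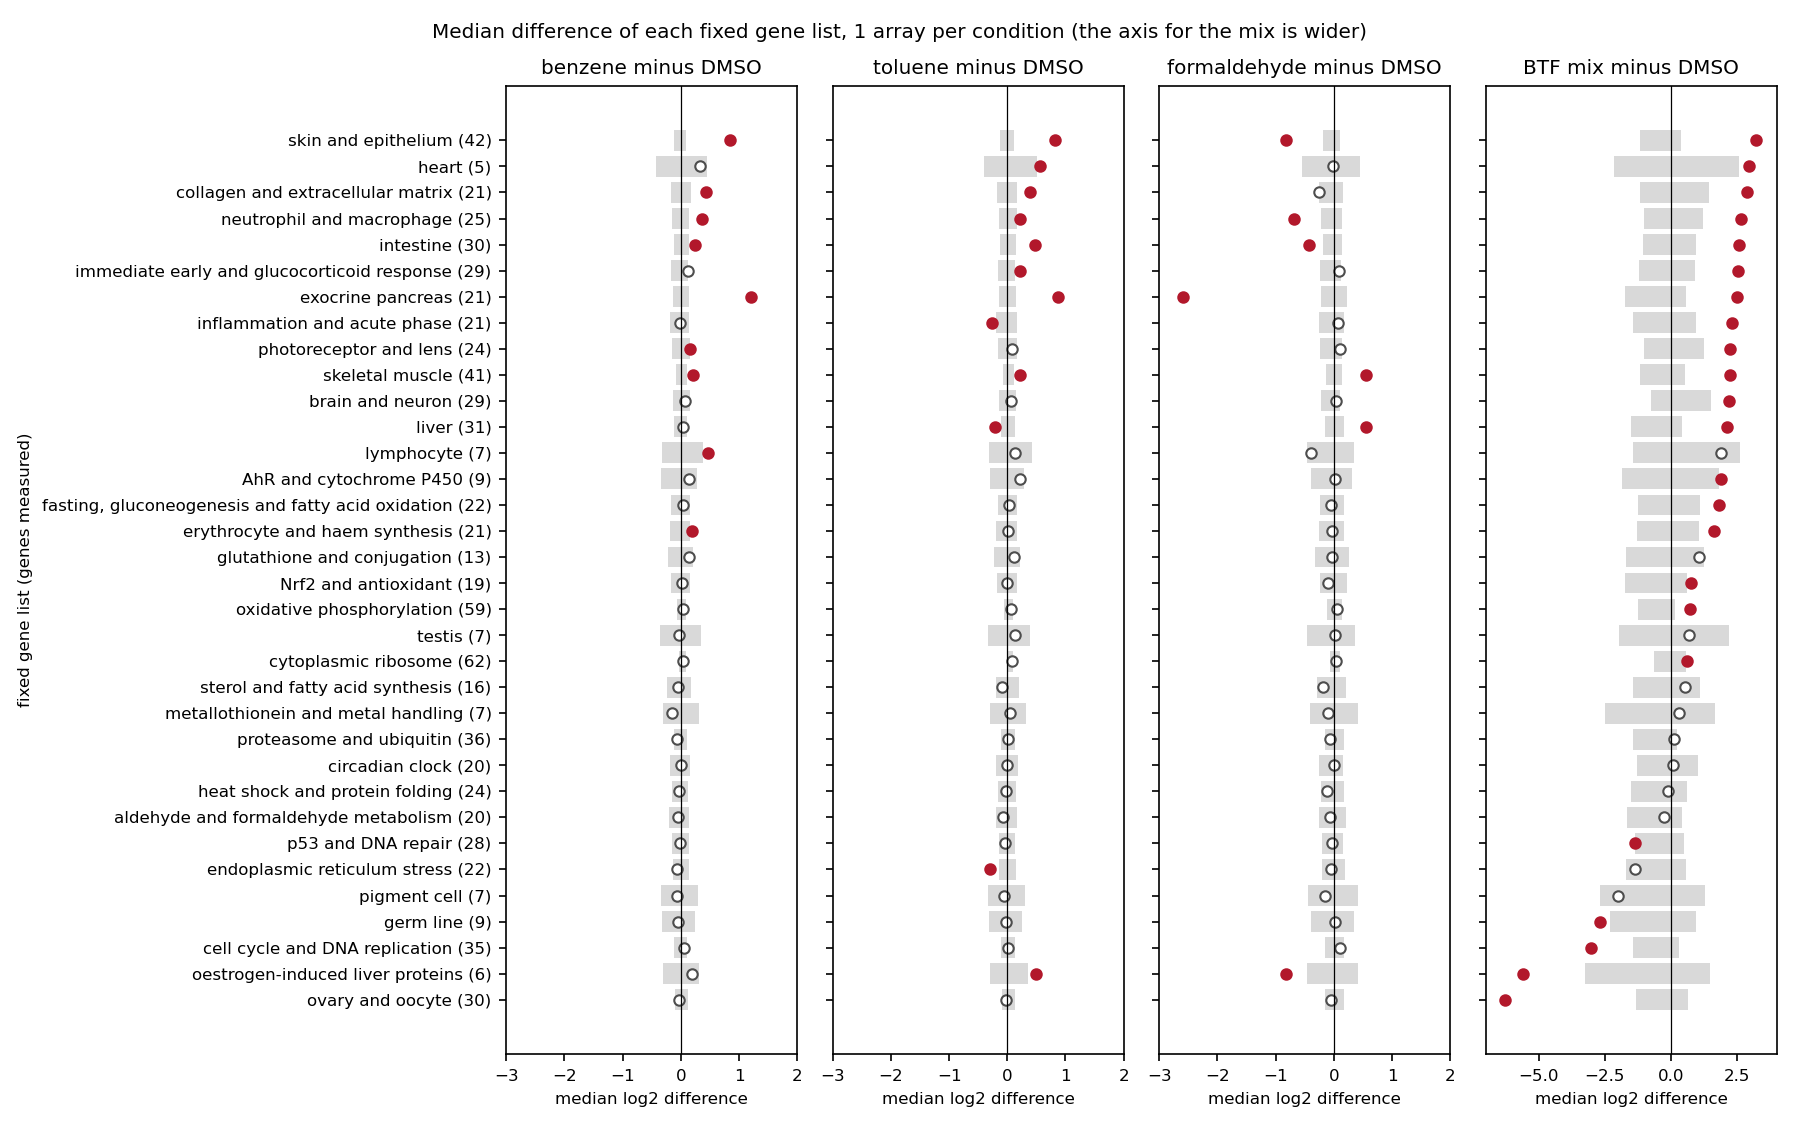
Median log2 difference from the DMSO array (horizontal axis) of 34 gene lists fixed beforehand (vertical axis, with the number of genes measured), 1 panel per exposure. Grey bars span the central 99% of 10000 random lists of the same size and mean level, and filled red points lie outside them; exocrine pancreas genes lie at 1.205 with benzene, 0.87 with toluene, -2.59 with formaldehyde and 2.49 with the mix.

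Differences below are log2 values of the exposed array minus the DMSO array. A list is said to stand apart when its median lies outside the central 99% of 10000 random gene lists of the same size matched on mean level. This describes these arrays and is no test, since genes of a list vary together. Of 34 lists, 0.34 would lie outside by the random draw alone.

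With benzene, digestive enzyme and skin genes were higher than with DMSO. Of the 21 measured genes of the exocrine pancreas, which makes the enzymes of digestion, 17 were at least 2-fold higher and 0 were at least 2-fold lower, with a list median of 1.205. They included the elastase cela1.5 at 2.09, the carboxypeptidase cpa5 at 1.77 and the bile salt-activated lipase cel.1 at 1.76. Of 42 skin and epithelium genes, 19 were at least 2-fold higher and 0 were at least 2-fold lower, with a list median of 0.85. Among these, the annexin anxa1b was higher by 2.37, the keratin krt17 by 2.07, the tight junction gene cldni by 2.03 and the actin-binding profilin pfn1 by 1.74.

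Smaller shifts in the same direction were seen with benzene in genes of other tissues. Collagen and extracellular matrix genes had a median of 0.43, with sparc, which binds collagen, at 1.03 and the matrix protease mmp2 at 0.94. Neutrophil and macrophage genes had a median of 0.37, with apoeb at 1.90 and s100a10b at 1.73. The intestine list lay at 0.24, where the fatty acid-binding protein fabp2 was higher by 0.89 and the retinol-binding protein rbp2a by 0.80. The skeletal muscle list lay at 0.21, with the calcium buffer pvalb2 at 0.79, and the lymphocyte list at 0.47, with gata3 at 0.70. Erythrocyte and haem genes lay at 0.19, where the carbonic anhydrase ca2 was higher by 1.21, and photoreceptor and lens genes at 0.16, where rpe65a was higher by 0.43 and the lens crystallin crybb1 lower, at -0.69. In all, 9 lists stood apart, all 9 higher.

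The largest single differences with benzene lay mostly outside those lists. Higher were mif4gda by 3.77, gcdhb (glutaryl-CoA dehydrogenase, an enzyme of lysine breakdown) by 3.34, spata2l by 3.30 (0.74 to 1.997 on its other probe sets), ipcef1 by 3.27, the retinal homeobox gene vsx1 by 2.999, the forkhead gene foxa by 2.83, the endoplasmic reticulum oxidase ero1a by 2.65, rtkn2 by 2.43, the gel-forming mucin muc5.1 by 2.301, fgfbp2a by 2.23 and the membrane skeleton gene add1 by 2.22. Lower were the class I MHC gene mhc1ufa at -5.19, zcchc10 at -3.47, the nuclear import receptor tnpo2a at -3.12, cdc42se1 at -2.99, kyat3.2 at -2.76, the complement component c7b at -2.30, the disulfide isomerase pdia6 at -2.16, the endosomal GTPase rab5b at -2.08, the glutathione peroxidase gpx1a at -2.08, adprm at -2.06 and the DNA end resection factor rbbp8 at -1.99. The vesicle coat gene copb2 had -2.91 on 1 probe set, but -0.06 and 0.03 on its other 2. In all, 203 probe sets were at least 2-fold higher with benzene and 98 were at least 2-fold lower.

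Against the mean of the toluene and formaldehyde arrays, a reference chosen after the data were examined, 238 probe sets were at least 2-fold apart with benzene. The skeletal muscle median had the opposite sign there, -0.30. The photoreceptor list did not stand apart against that reference, nor after quantile or loess normalization. Against the mean of all 3 other exposed arrays, which includes the mix, the count was 924 and 8 of the 9 lists had the opposite sign, and the lymphocyte, erythrocyte and photoreceptor lists did not stand apart with no level filter.

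With toluene, the same pair of tissue lists was higher, and genes of the intestine and of the immediate early and glucocorticoid list were higher as well. Neither is particular to toluene: the intestine list also stood apart with benzene. The immediate early and glucocorticoid list lay at 0.12 with benzene, just inside its random lists. The exocrine pancreas list had a median of 0.87, with 7 of 21 genes at least 2-fold higher, among them ela2 (elastase) at 1.54, the phospholipase pla2g1b at 1.39 and cpa5 at 1.14. The skin and epithelium list had a median of 0.81, with 15 of 42 genes at least 2-fold higher, such as cldni at 2.08, anxa1b at 1.79, anxa1a at 1.502 and capn9 at 1.48. Of 30 intestine genes, 7 were at least 2-fold higher, with a list median of 0.47; the chitinase chia.3 was higher by 2.91, the brush border phosphatase alpi.2 by 2.21, fabp2 by 2.11 and fabp1b.1 by 1.92. No member of these 3 lists was at least 2-fold lower with toluene.

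Of 29 immediate early and glucocorticoid response genes, 6 were at least 2-fold higher with toluene, with a list median of 0.21. These included the transcription factors klf2a at 2.44, cebpd at 2.14 and klf9 at 2.01, and the glucocorticoid receptor cochaperone fkbp5 at 1.92; the only other probe set for cebpd differed by -0.07. The gluconeogenic enzyme pck1 was higher by 1.97 and the pyruvate dehydrogenase kinase pdk2b by 1.00, while hadhaa, an enzyme of fatty acid oxidation, was at -1.07 and igfbp1b at -0.93, in a list for fasting that did not stand apart (median 0.03). Collagen and matrix genes lay at 0.39 with sparc at 1.297 and col10a1a at 1.14, skeletal muscle at 0.22 with pvalb2 at 1.22, heart at 0.55 with the myosin light chain myl7 at 0.70, and neutrophil and macrophage genes at 0.22 with s100a10b at 1.69 and cxcr4b at 1.095.

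The liver was split with toluene. The list of liver proteins induced by oestrogen lay at 0.49, with the aspartic protease nots at 1.58 and the vitellogenins vtg4 at 1.17 and vtg3 at 0.69. The list of other liver genes lay at -0.22, although 3 of its 31 genes were at least 2-fold higher, namely the apolipoproteins apoea at 2.27 and apoeb at 1.53 and the retinol carrier rbp4 at 1.00; kng1, a kininogen, was at -0.89. Inflammation and acute phase genes lay at -0.27, with the interferon-stimulated isg15 at -1.77 and the complement component c9 at -0.98, against cfd at 1.05. Endoplasmic reticulum stress genes lay at -0.30, with sel1l at -1.03, the transcription factor atf4a at -0.80 and the stress kinase eif2ak3 at -0.63. In all, 12 lists stood apart with toluene, 9 higher and 3 lower.

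The largest single increases with toluene were those of the class I MHC gene mhc1zba by 4.77, the homeobox gene dlx6a by 4.19, rundc3ab by 2.97, chia.3, spata2l by 2.84 (0.11 to 2.19 on its other probe sets), klf2a, the keratin krt1-19d by 2.34, apoea, ipcef1 by 2.24, alpi.2, cebpd and ptgdsb.1 by 2.14. The lowest were mhc1ufa at -5.30, the interferon-induced ifi44a6 at -2.90, tnpo2a at -2.49, pik3r3b at -2.38 (-0.76 on its other probe set), cimap1b at -1.97, isg15, irg1l at -1.71, trpt1 at -1.70, mfap4.5 at -1.62, the neuropeptide gene tac3b at -1.60, the lysosomal gene psap at -1.56 and the elongation factor eef1a1b at -1.48. In all, 205 probe sets were at least 2-fold higher with toluene and 76 at least 2-fold lower.

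Against the mean of the benzene and formaldehyde arrays, also chosen after the data were examined, the toluene count was 241 and the skeletal muscle median had the opposite sign, -0.11; against the mean of all 3 other exposed arrays the count was 961, 7 of the 12 lists had the opposite sign, and the pancreas, intestine, heart and endoplasmic reticulum stress lists did not stand apart. With no level filter the collagen (0.04), oestrogen-induced (0.28) and heart lists did not stand apart, and the heart list, with 5 genes, did so under no alternative in which it could be described.

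Toluene differs from benzene by 1 methyl group. The doses are not given, so their arrays can only be set side by side. Between them, 101 probe sets were at least 2-fold higher with toluene and 71 were at least 2-fold higher with benzene, out of 9716. The 2 compounds lay close in the skin list (median of toluene minus benzene -0.06) and in skeletal muscle (0.08), both outside their random lists even so. They lay further apart in the exocrine pancreas (-0.37), inflammation (-0.28), liver (-0.26), endoplasmic reticulum stress lists (-0.23) and in neutrophil and macrophage genes (-0.16), all lower with toluene. Liver proteins induced by oestrogen lay higher with toluene (0.29), as did the intestine list (0.14), where 5 of 30 genes were at least 2-fold higher with toluene. With no replicate, none of these differences can be set against the spread between arrays of 1 condition.

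Single genes showed larger gaps between the 2 aromatic compounds. Higher with toluene than with benzene were mhc1zba by 4.67, zcchc10 by 3.05, kyat3.2 by 2.95, acbd4 by 2.83, adprm by 2.59, rundc3ab by 2.56, rab5b by 2.43, dlx6a by 2.38, c7b by 2.302, gpx1a by 2.29 and klf9 by 2.15. The copb2 probe set named above differed by 2.78, against -0.18 and 0.00 for its other 2. Lower with toluene were ifi44a6 at -3.05, vsx1 at -2.77, ero1a at -2.70, gcdhb at -2.52, the calcium channel cacna1ha at -2.04, mif4gda at -1.92, pik3r3b at -1.65, igfbp1a at -1.64, foxa at -1.63, tmem54a at -1.63, c4 at -1.58 and selenop2 at -1.51.

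With formaldehyde, genes of the exocrine pancreas, skin, intestine and neutrophils, which were higher with benzene and toluene, were lower than with DMSO, while skeletal muscle genes were higher with all 3 compounds. Of 21 exocrine pancreas genes, 20 were at least 2-fold lower, with a list median of -2.59. The digestive proteases led them, with the chymotrypsinogen ctrb.1 at -4.60, the carboxypeptidases cpa5 at -4.14 and cpa1 at -3.45, the elastases cela1.6 at -3.90, ela2 at -3.47, ela3l at -3.19 and ela2l at -2.85, ctrl at -3.15 and the trypsin prss1 at -3.11, and the lipase cel.1 lay at -2.91. Of 42 skin and epithelium genes, 16 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.81; the keratins krt91 and krt5 lay at -2.84 and -2.47 and icn2 at -2.15. Elastases, trypsins and keratins belong to families with similar sequences, so a probe set can also bind a relative's transcript.

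Neutrophil and macrophage, gut and egg yolk genes were lower with formaldehyde, and muscle and liver genes were higher. Of 25 neutrophil and macrophage genes, 8 were at least 2-fold lower, with a median of -0.68; besides cpa5, which is on this list too, they included cd74a at -1.81 and cd74b at -1.80, the invariant chain of class II MHC, and the collagenase mmp13a at -1.73. The class II MHC gene mhc2daa lay at -2.92. The intestine list had a median of -0.43, with chia.1 at -2.01, the cadherin cdh17 at -1.66, tm4sf4 at -1.59 and fabp2 at -1.42. The list of liver proteins induced by oestrogen lay at -0.82, with vtg3 at -1.91, vtg4 at -1.67 and vtg2 at -1.32, and nots at 0.80. Skeletal muscle genes lay at 0.55, with 10 of 41 at least 2-fold higher, such as pvalb2 at 1.64, the troponins tnni2a.3 at 1.62 and tnnc2.2 at 1.61 and the myosin-binding mybpc2b at 1.46. Liver genes also lay at 0.55, with apom at 1.23, the antithrombin serpinc1 at 1.18, the haem carrier hpxa at 1.16 and the tyrosine aminotransferase tat at 1.15.

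Another 3 lists had at least 3 members 2-fold apart with formaldehyde without standing apart. Collagen and matrix genes lay at -0.26, with sparc at -1.17, col1a1a at -1.14 and postnb at -1.06, against matn1 at 1.02; this list did stand apart after quantile normalization (-0.23), with no level filter (-0.16), with the mean of a gene's probe sets (-0.31) and against other reference arrays. In the inflammation list, at 0.07, cfd lay at -1.94 and isg15 at -1.43, while c4 was at 0.78. In the erythrocyte and haem list, at -0.04, the haem synthesis enzyme alas1 lay at -1.39 and cahz at -1.15, while tmod4 was higher by 1.14. In all, 7 lists stood apart with formaldehyde, 2 higher and 5 lower.

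The largest single increases with formaldehyde were those of mif4gda by 4.57, dlx6a by 4.28, mhc1zba by 3.81, spata2l by 3.65, gcdhb by 3.12, ipcef1 by 3.12, rundc3ab by 2.87, the TRIM family gene ftr81 by 2.59, foxa by 2.25, svbp by 2.07, the Hsp110 family chaperone hspa4a by 1.99 and the cytochrome P450 gene cyp2k6 by 1.98. The gene mhc1ufa was lower, at -5.03. In all, 150 probe sets were at least 2-fold higher with formaldehyde and 221 were at least 2-fold lower. Among the 4 arrays without the mix, 149 probe sets were at least 2-fold lower with formaldehyde than on each of the other 3, against 27 for DMSO, 27 for benzene and 8 for toluene.

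Against the mean of the benzene and toluene arrays, a reference chosen after the data were examined, the formaldehyde array had 106 probe sets at least 2-fold higher and 357 at least 2-fold lower. Against the mean of all 3 other exposed arrays the count was 1874, the liver and skeletal muscle lists no longer stood apart, and the skeletal muscle median had the opposite sign, -0.15, as did that of the liver proteins induced by oestrogen, 0.40, a list that did not stand apart with no level filter either (-0.31).

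**Figure D2:**
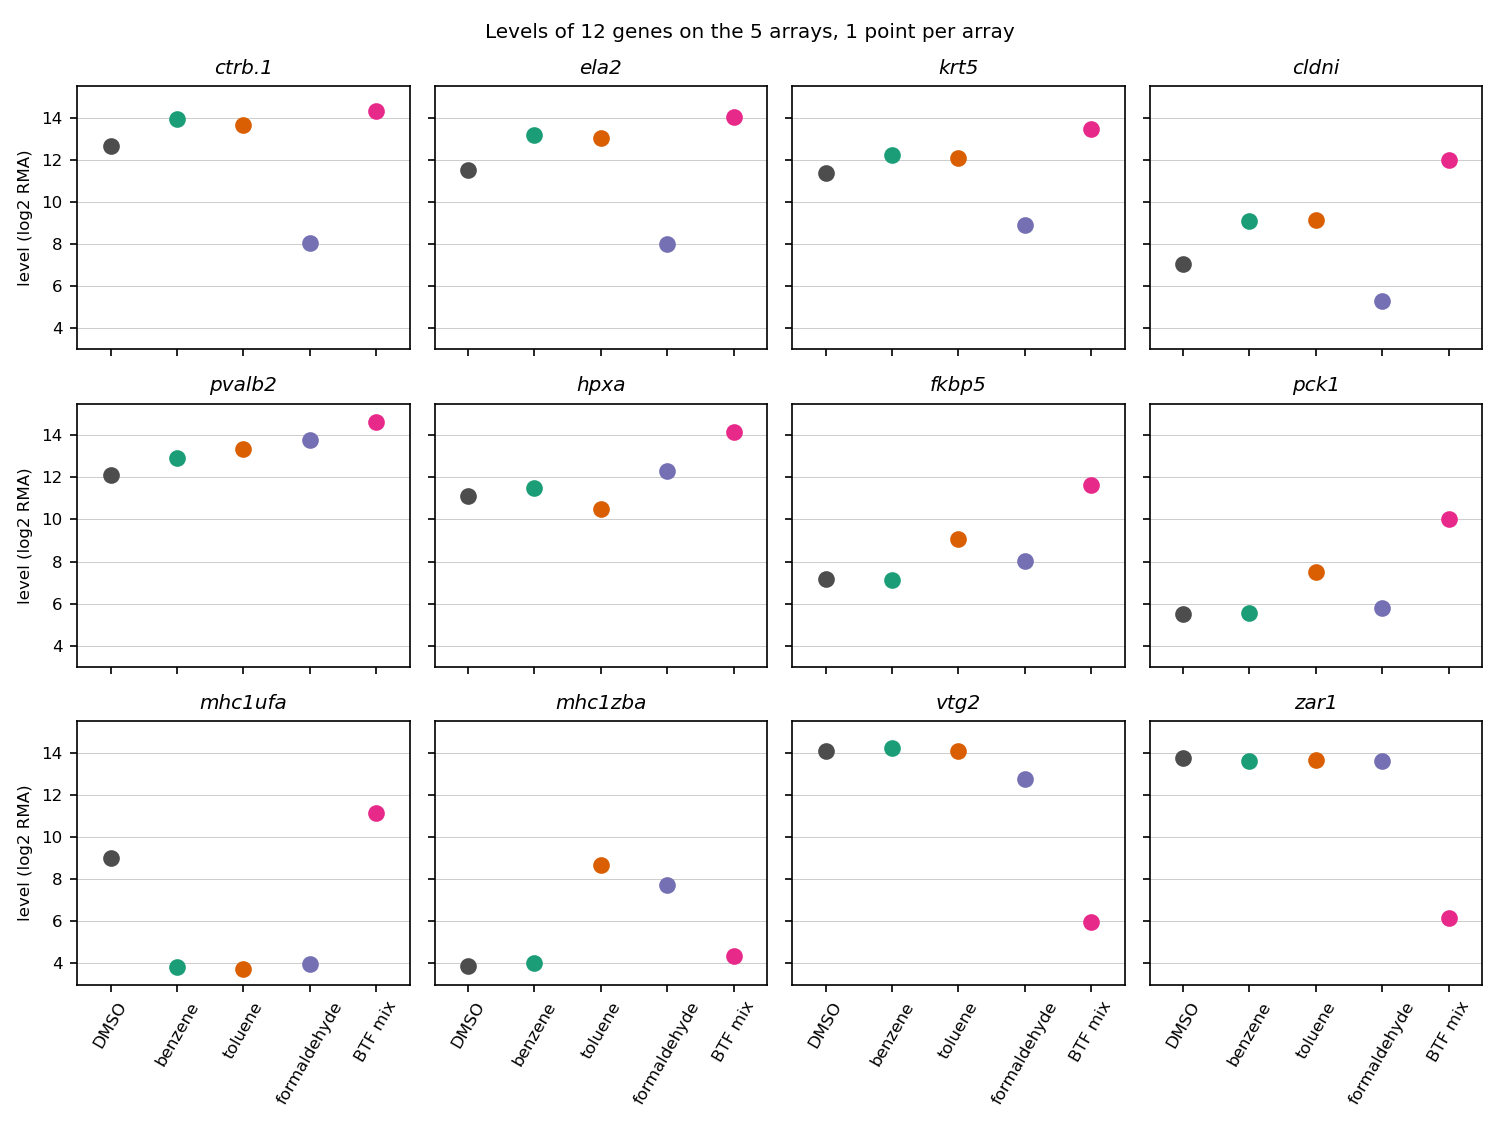
Levels (log2, vertical axis) of 12 genes on the 5 arrays (horizontal axis), 1 point per array with no replicate. The pancreas gene ctrb.1 had -4.60 with formaldehyde relative to DMSO, and the class I MHC gene mhc1ufa -5.19 with benzene. With the mix, the oestrogen-induced liver gene vtg2 had -8.12 and the oocyte gene zar1 -7.60.

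The lists for the aryl hydrocarbon receptor, DNA repair, heat shock and aldehyde metabolism stayed within their random lists on the 3 single-compound arrays, unlike the endoplasmic reticulum stress list with toluene (-0.30). Medians with benzene, toluene and formaldehyde were 0.14, 0.21 and 0.02 for the aryl hydrocarbon receptor and cytochrome P450 list, -0.02, -0.05 and -0.03 for the p53 and DNA repair list, and -0.04, -0.03 and -0.12 for the heat shock list. For aldehyde and formaldehyde metabolism they were -0.05, -0.08 and -0.07. The receptor's best-known target cyp1a differed by 0.28, 0.31 and 0.02 in the same order, and adh5, which oxidises formaldehyde bound to glutathione, by -0.07, -0.08 and -0.17. Within the metabolism lists, mthfd2 was higher by 1.58 and cyb5a by 1.25 with toluene, and aldh8a1 lay at -1.50 with benzene; these 5 genes were chosen outside the naming rule, the last 3 after their values were seen. With formaldehyde, cyp2k6 of the receptor list and adh8b of the aldehyde list were at least 2-fold higher. The heat shock list member hspa4a was higher by 1.77 with benzene, 1.76 with toluene and 1.99 with formaldehyde. Of the listed genes, 9 of 35 were measured for the receptor list and 20 of 33 for the aldehyde list. Without replicates, the size of a shift that would have gone unseen cannot be stated.

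With the BTF mix, transcripts of eggs and of egg yolk were far lower and transcripts of most other tissues were higher. Of 30 ovary and oocyte genes, 27 were at least 2-fold lower and 3 at least 2-fold higher, with a median of -6.26. The maternal factor zar1l lay at -7.99, the egg coat gene zp3c at -7.65, the zinc finger gene cth1 at -7.61 and zar1 at -7.60. The list of liver proteins induced by oestrogen lay at -5.60, with vtg2 at -8.12, zp2l1 at -7.50, vtg4 at -6.42 and vtg3 at -4.77. Germ line genes lay at -2.69, with nanos3 at -5.19, dazl at -3.90, tdrd7a at -3.46 and rnf17 at -3.23, RNA-binding and Tudor proteins of germ cells. Of 35 cell cycle and DNA replication genes, 32 were at least 2-fold lower, with a median of -3.01, and the leading ones were gmnn (geminin) at -6.62, the cyclins ccnb2 at -6.54 and ccna1 at -5.87, and birc5b (survivin) at -6.10.

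Genes of 11 body tissues were higher with the mix, with list medians from 1.64 to 3.22, while the pigment cell and testis lists lay at -2.01 and 0.67. The medians were 2.22 for skeletal muscle, 2.11 for liver, 2.21 for brain and neuron, 2.22 for photoreceptor and lens, 2.49 for exocrine pancreas, 2.57 for intestine, 2.67 for neutrophil and macrophage, 2.94 for heart, 1.64 for erythrocyte and haem and 3.22 for skin, each standing apart, and 1.89 for lymphocyte, which did not. Collagen and matrix genes, a list for a function, lay at 2.87. With no level filter, pigment cell genes lay at 0.16, and erythrocyte (0.66) and heart genes (1.33) did not stand apart. Lymphocyte (0.91) and brain and neuron genes (1.38) were then still higher, but by less. Examples were the sarcoplasmic calcium pump atp2a1 at 3.36, smyhc1 (slow myosin) at 3.17, the fibrinogen chain fgg at 3.48, the haem carrier hpxa at 3.01, the neuronal olfm1b at 3.41, the myelin gene mbpa at 2.57, the cone phosphodiesterase pde6c at 3.09, the lens gene cryaa at 3.004, the pancreatic pla2g1b at 3.55, agr2 of the gut at 4.81, lysozyme (lyz) at 4.13, hbba2 (beta globin) at 4.51, myl7 at 3.36 and the skin genes lye at 5.51, capn9 at 5.26 and cldni at 4.93. An exception in the intestine list was chia.4, at -7.97.

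**Figure D3:**
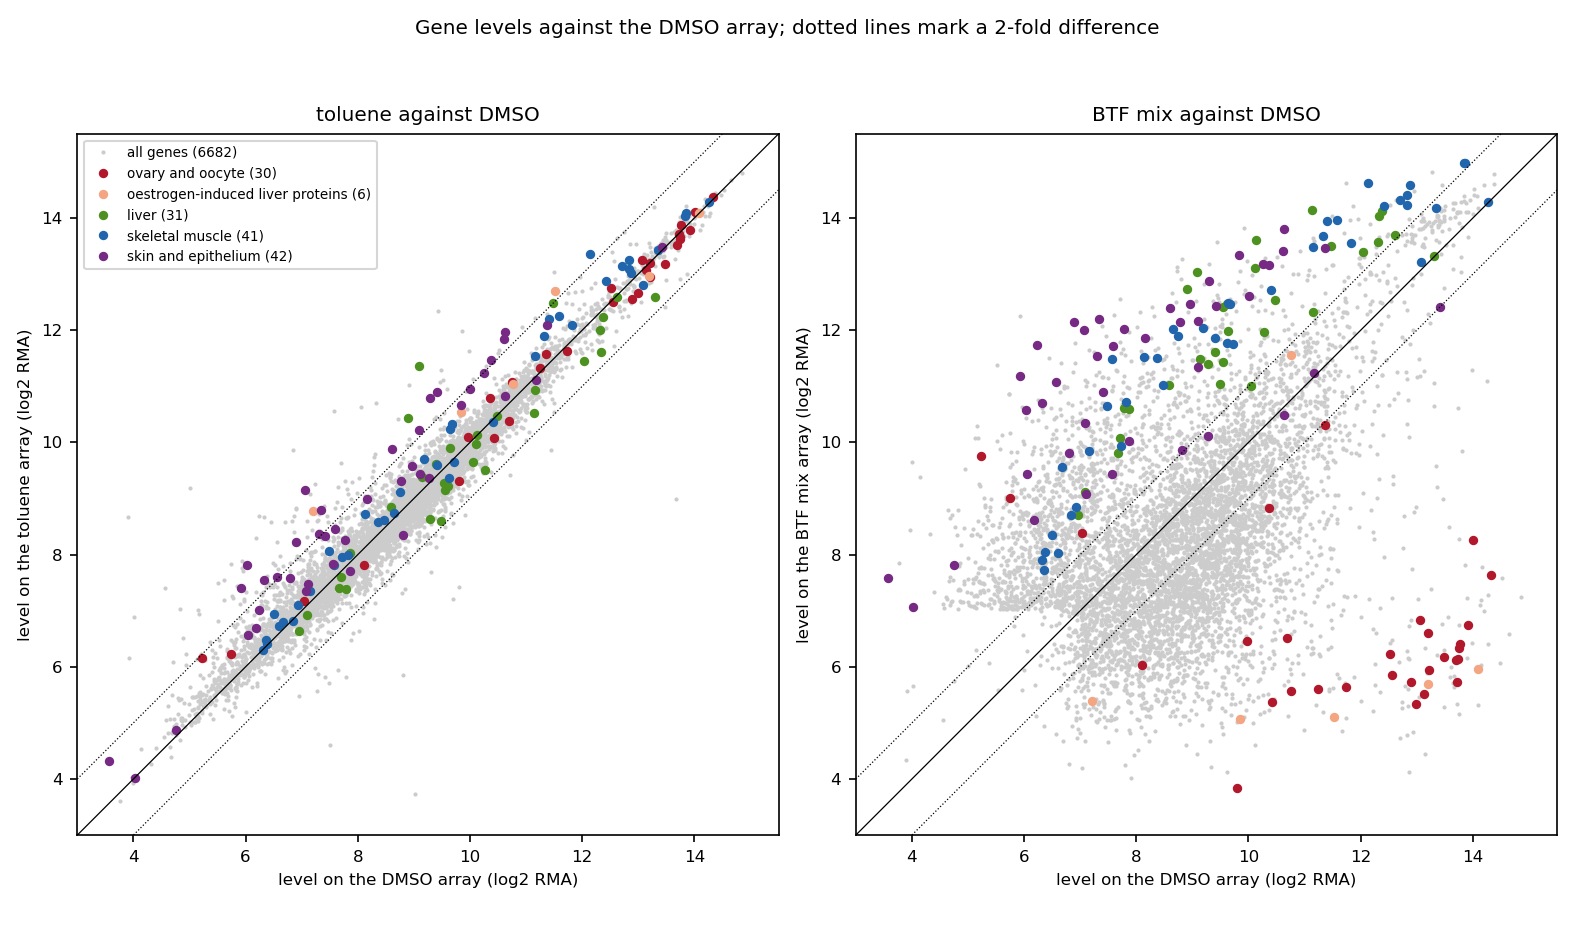
Level of each of 6682 genes on the DMSO array (horizontal axis, log2) against the toluene array (left) and the BTF mix array (right, both vertical axes log2), with 5 gene lists in colour and dotted lines at a 2-fold difference. With the mix, ovary genes (median -6.26) and liver proteins induced by oestrogen (-5.60) fall below the diagonal, and liver (2.11), muscle (2.22) and skin genes (3.22) lie above it.

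Genes of the glucocorticoid response, fasting and inflammation were higher with the mix, and can be set beside the 11 body tissue lists, whose medians centred on 2.22. Of 29 immediate early and glucocorticoid response genes, 22 were at least 2-fold higher, with a median of 2.53; cebpd lay at 5.05 (0.57 on its other probe set), fkbp5 at 4.49, klf9 at 4.38 and socs3a, a brake on cytokine signalling, at 4.27. The fasting list lay at 1.84, with the muscle ubiquitin ligase trim63a at 5.13, pdk2b at 4.95, pck1 at 4.51 and igfbp1a at 4.32, against hadhaa at -1.28. Of 21 inflammation and acute phase genes, 18 were at least 2-fold higher, with a median of 2.33, such as the proteases mmp13a at 3.80 and mmp9 at 3.76 and the complement genes c4 at 3.30 and c6.2 at 3.28. The aryl hydrocarbon receptor and cytochrome P450 list lay at 1.89, with cyp3a65 at 3.09, the receptor gene ahr2 at 2.88, cyb5a at 2.13 and cyp1a at 2.098, and cyp2k6 at -1.10; with no level filter its median was 0.63, and it stood apart neither then nor against the mean of the other 3 exposed arrays. The Nrf2 and antioxidant list lay at 0.78, with prdx5 at 3.46, nfe2l2a at 2.94, gpx1a at 2.55 and nqo1 at 2.53.

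Lists for basic cell functions showed smaller medians with the mix. Oxidative phosphorylation genes lay at 0.72, with cox8a at 2.79 and cox6b1 at 2.51, and cytoplasmic ribosome genes at 0.62, with rpl5a at 1.32. The p53 and DNA repair list lay at -1.34, with the checkpoint kinases chek1 at -3.05 and chek2 at -2.82 and the uracil glycosylase unga at -2.98, against gadd45ba at 4.02. The ribosome and DNA repair lists stood apart on the deposited values, and not after quantile or loess normalization; the DNA repair list did not with no level filter or against the mean of the other 3 exposed arrays either. In all, 23 lists stood apart with the mix, 18 higher and 5 lower.

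Several lists with members 2-fold apart did not stand apart with the mix. The glutathione list lay at 1.05, with sult2st1 at 3.15 and gstk1 at 3.06, and did stand apart after quantile normalization (1.32) and with no level filter (1.09). Endoplasmic reticulum stress genes lay at -1.36, with the asparagine synthetase asns at -3.88, pdia4 at -3.28, hsp90b1 at -2.49 and hspa5 at -2.10. Heat shock genes lay at -0.10, with hsp90aa1.2 at 2.85 and hsp70.3 at 2.24, against dnajb1b at -2.28. The circadian clock list lay at 0.08, with bhlhe41 at 3.17 and bhlhe40 at 2.94, against bmal1a at -2.45. Aldehyde metabolism genes lay at -0.25, with mthfd2 at 3.23 and adh8b at 2.28, against aldh18a1 at -2.94. The sterol synthesis list lay at 0.52, with nsdhl at -2.65 and mvk at -2.44, and the metal handling list at 0.29, with the ferritin gene fthl28 at 3.46 and the iron exporter slc40a1 at 2.43. Proteasome and ubiquitin genes lay at 0.13, with the immunoproteasome subunits psmb8a at 3.28 and psmb9a at 2.71, and stood apart after loess (0.78), and the pigment cell list at -2.01, with scarb1 at -4.64 and slc2a15b at -4.56. In the testis list, at 0.67, ldhbb lay at 3.77 and star at 3.498, against cyp17a1 at -4.96.

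The largest single increases with the mix were those of fgfbp2a by 6.32, selenop2 by 5.87, lye, anxa2a by 5.26, capn9, the collagen cross-linking enzyme loxa by 5.24, trim63a, the glycolytic regulator pfkfb3 by 5.12 (0.57 on its other probe set), cebpd, pdk2b, cldni and cldnb by 4.86. The lowest, besides the egg and yolk genes above, were a2m3a at -8.20, zpax1 at -7.86, qdprb.4 at -7.83, zpax4 at -7.74, zp3.1 at -7.62 and chia.4. The gene sptan1 had -7.93 on 1 probe set and 0.32 on the other. In all, 2573 probe sets were at least 2-fold higher and 3201 at least 2-fold lower, together 59.4% of the 9716.

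These counts depend on where 0 is placed, which the RMA values fix by the total signal of each array. With differences centred on the tissue lists (2.22), a choice made after the data were examined, 310 probe sets were at least 2-fold higher and 7450 at least 2-fold lower, so 3.99% of the counted ones were higher, against 44.6% without it. Loess normalization moved the mix difference by a median of -0.15 over all probe sets, but moved the median difference of those past the filter from -0.22 to 0.17, and 54.2% of its counted ones were higher.

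Whether the mix array held the differences seen with its single compounds was asked across probe sets. All comparisons share the DMSO array, so unchanged arrays would correlate too, at 0.50 in simulation. The observed correlations across 9716 probe sets were 0.69 for benzene with toluene, 0.27 for benzene with formaldehyde and 0.33 for toluene with formaldehyde. With the mix they were 0.34 for benzene, 0.32 for toluene and -0.03 for formaldehyde. The 0.50 is no yardstick for these, since the simulated mix array had the small noise of the other arrays. The real mix differences had an SD of 2.01 over probe sets, against 0.43 for benzene. Spearman correlations were 0.409 for benzene with formaldehyde and 0.459 for toluene with formaldehyde, nearer to 0.50. The covariance was 0.121 for benzene with toluene, against 0.0539 simulated for unchanged arrays, 0.0558 against 0.0538 for benzene with formaldehyde, 0.0654 against 0.0539 for toluene with formaldehyde, 0.290 against 0.0537 for benzene with the mix, 0.266 against 0.0538 for toluene with the mix, and -0.0281 against 0.0537 for formaldehyde with the mix. The simulated noise came from the benzene and toluene pair, whose difference had an SD of 0.33. Other pairs of the arrays without the mix had 0.41 to 0.55. The excess for benzene with toluene thus restates that these arrays lay closer to each other than to DMSO. Genes are not independent replicates, and only 1 DMSO array exists, so it cannot be split.

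Comparisons that share no array gave the same order of compounds. The difference of mix minus toluene correlated at 0.21 with benzene minus DMSO, and that of mix minus formaldehyde at 0.26. Toluene minus DMSO correlated at 0.19 with mix minus benzene and at 0.24 with mix minus formaldehyde. Formaldehyde minus DMSO correlated at -0.09 with mix minus benzene and at -0.10 with mix minus toluene. The exocrine pancreas and skin lists were higher with benzene, with toluene and with the mix, and lower with formaldehyde. Correlations and overlaps with the mix thus cannot tell an effect of a compound from a difference in tissue make-up between arrays. The order differed between tissues: for benzene, toluene, formaldehyde and the mix, the exocrine pancreas list lay at 1.205, 0.87, -2.59 and 2.49, the skeletal muscle list at 0.21, 0.22, 0.55 and 2.22, and the liver list at 0.03, -0.22, 0.55 and 2.11. The slope of the mix difference on the mean of the 3 single differences was 1.48, against 0.75 in simulated unchanged arrays. On their sum it was 0.49, against 0.25 simulated. The correlation was 0.25, so most of the mix difference did not follow the single differences, and neither slope measures an enlarged or additive effect.

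The lists of probe sets at least 2-fold apart overlapped. Benzene and toluene shared 117 higher and 38 lower probe sets, where independent lists of those sizes would share 4.28 and 0.767, and 1 probe set went opposite ways. Benzene and formaldehyde shared 39 higher and 34 lower ones, against 3.13 and 2.23, with 57 going opposite ways, and toluene and formaldehyde shared 40 and 34, against 3.16 and 1.73, with 46 opposite. With the mix, benzene shared 151 and 62, against 53.8 and 32.3, toluene 155 and 42, against 54.3 and 25.04, and formaldehyde 79 and 51, against 39.7 and 72.8, with 168 opposite. Over both directions, simulated unchanged arrays with a common DMSO array shared 7.27 probe sets for benzene with toluene, 7.55 for benzene with formaldehyde, 7.48 for toluene with formaldehyde, and 6.93, 7.19 and 6.85 for benzene, toluene and formaldehyde with the mix. The simulated mix array had the noise of the other arrays. Its shared counts thus do not allow for the 5774 probe sets counted with the mix. With 1 control array, the part of each excess that comes from the shared array cannot be split off.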

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

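All tests in this part were chosen after the results were seen, except the test of neighbouring genes, whose possible outcomes were set down before it was run. Control probe sets, left out of the comparisons, were higher than with DMSO for some zebrafish genes. With the mix, 4 control probe sets for muscle actin were higher by 1.21, 3.82, 2.83 and 1.73, and 3 for GAPDH by 3.71, 3.59 and 3.86. Another 2 zebrafish control probe sets were higher with the mix by 1.04 and 1.52. The actin control's 3' probe set exceeded its 5' probe set by 3.40 with the mix, against 6.02 with DMSO, 5.63 with benzene, 5.77 with toluene and 5.73 with formaldehyde; for GAPDH this gap was 0.64, 0.51, 0.53, 0.58 and 0.43 in the same order, so the pair does not give one reading of RNA quality. With formaldehyde the 4 actin probe sets were higher by 0.65, 0.94, 1.16 and 0.95. The 3 GAPDH probe sets were higher by 0.87, 0.85 and 1.02 with benzene and by 0.79, 0.72 and 0.94 with toluene. With formaldehyde they lay at -0.47, -0.39 and -0.26.

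The mix array was low in oocyte (median -6.26) and yolk protein transcripts. The arrays' normalization is argued against by the hybridization controls, which shifted by a median of 0.39 (SD 0.29 over 18 probe sets). Leaving the ovary out of fish with an active one is argued against by the liver: its proteins induced by oestrogen lay -7.71 from the other liver genes (SD 0.86 over these). A smaller share of ovary RNA, as in male or non-vitellogenic fish, would raise all other tissues alike, and no value here decides it: that 11 of 11 body tissue lists lay within 1 SD over genes of their centre was nearly assured, since they were chosen after their medians (1.64 to 3.22) were seen, and the pigment cell list lay -4.23 from it, with 4 of its 7 measured genes serving purine synthesis in any cell; the testis list lay at 0.67 (7 of 32 genes measured) and did not stand apart. With no level filter the pigment cell list lay at 0.16 over 18 genes, so its place apart depends on the filter. A smaller share of ovary RNA and an effect of the mixture on the ovary cannot be told apart. There is 1 mix array, and the labels' single entry for sex names no male or female group.

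The formaldehyde array was low in pancreas, gut and skin transcripts. A DMSO array that stands apart is argued against by the pancreas list, which lay at -3.36 (SD 1.29 over genes) against the mean of benzene and toluene. Less body tissue in general is argued against by muscle and liver, whose smaller median was 0.55. Less pancreas, gut and skin in the extracted tissue may account for it and cannot be told apart from lower expression: 4 of 8 islet genes were measured, with a median of -0.47 (SD 0.26), far from the -2.59 of the pancreas list, but they are few, 3 of them lay under the 7.02 of the filter with DMSO, where a fall is compressed, and none speaks for gut or skin; these were ins at -0.80, sst1.1 at -0.60, sst2 at -0.34 and gcga at -0.22. A direct effect of formaldehyde on these genes was not tested, with 1 array at hand.

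Some genes were near the background on 1 or more arrays and far above it on others. The genes counted here were chosen by the size of the gap alone, so not all of them came near the background. An example is chia.3, with levels of 9.44 with DMSO, 10.48 with benzene and 12.34 with toluene. Among the DMSO, benzene and toluene arrays, 27 genes differed by at least 2.5; mhc1ufa had levels of 9.02 with DMSO, 3.83 with benzene, 3.72 with toluene, 3.99 with formaldehyde and 11.17 with the mix, and mhc1zba 3.90, 4.001, 8.67, 7.71 and 4.33. A different mix of the listed tissues cannot be told apart from other causes: the largest list median among these 3 arrays, 1.205 (SD 0.53 over genes), was too small for gaps of 2.5 and 3 by the rule used but not for a gap of 2, and the gap was picked after the counts of 56, 27 and 14 genes were seen. Linked haplotypes that differ between fish would bring neighbouring genes together, and this cannot be told apart from its absence: 7.69% of 26 genes had another of them within 10 measured genes, against a median of 7.69% in random gene sets, and with gaps of 2 and 3 the share was 7.27% and 0%, against random medians of 14.55% and 0%; the bound set beforehand, the random median, was met without being passed by the spread of random sets (95th percentile 23.08%). Sequence variants limited to 1 gene, and single failing probe sets as with copb2, may remain, and 24 of the 27 genes have only 1 probe set.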

How the results depend on the processing

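The references that leave out DMSO and the mix, the level filter without the mix array and the centring on tissue lists were chosen after the data were examined, and the others before. No paired analysis was possible because each group has 1 array and no result comes from a test. Of 124 recomputed values other than named genes, 106 stayed close to the reported ones (counts within 1.5 times, correlations within 0.1) and 18 moved. For counts this compares totals only. The mix centred on tissue lists counts as close, although its higher probe sets went from 2573 to 310. So does toluene against the other 3 exposed arrays, with 18 lists against 12, although several lists had the opposite sign. Counts moved with the threshold by construction: at 1.5-fold they were 912 (benzene), 918 (toluene), 1244 (formaldehyde) and 513 (toluene against benzene), and at 3-fold 101, 83, 128 and 54. With 1 probe set per gene, fewer items were counted, 199 for benzene and 184 for toluene, and with the 75th percentile filter the mix count was 3657. The mean of the other 3 exposed arrays as reference gave 924, 961 and 1874 probe sets and 18 lists for benzene and 20 for formaldehyde, since the mix enters that reference. Spearman correlations were 0.409 for benzene with formaldehyde and 0.459 for toluene with formaldehyde; the cause was not tested. Lists that stopped standing apart under a scaling were erythrocyte and photoreceptor (quantile) and photoreceptor (loess) for benzene, heart for toluene (both), and ribosome and p53 for the mix (both). With no level filter, those were erythrocyte, lymphocyte and photoreceptor for benzene, collagen, heart and oestrogen-induced for toluene, oestrogen-induced for formaldehyde, and aryl hydrocarbon receptor, erythrocyte, heart and p53 for the mix; with the filter without the mix array, erythrocyte and photoreceptor for benzene. The lymphocyte list for benzene (loess, filter without the mix) and the heart list for toluene (filter without the mix) had under 5 genes there and were not described. Against the other 3 exposed arrays, the mix lost the aryl hydrocarbon receptor and p53 lists. Lists gained were glutathione (quantile, no filter) and proteasome (loess) for the mix, heart and immediate early for benzene (no filter), and collagen for formaldehyde (quantile, no filter, mean of probe sets, filter without the mix, which also gained photoreceptor). Against the other 2 single-compound arrays, benzene gained inflammation and liver and lost photoreceptor. Formaldehyde gained collagen and lymphocyte there, and toluene lost heart. Loess moved the median difference of the mix from -0.22 to 0.17, and the higher share of its calls from 44.6% to 54.2%. All 356 named differences kept their sign under both scalings. The pseudocount alternatives were not run, since the values are logarithmic. The number of arrays, 1 per group, limits all of these.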

Other observations

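The genes in this part were chosen after their values were seen. A few genes known to respond to glucocorticoids or fasting were higher with toluene than with benzene, although neither fixed list stood apart between these arrays (median of toluene minus benzene 0.03 for the glucocorticoid list and 0.05 for the fasting list). The cochaperone gene fkbp5 had levels of 7.16 with DMSO, 7.12 with benzene, 9.08 with toluene, 8.04 with formaldehyde and 11.65 with the mix. In the same order, klf9 had 7.24, 7.11, 9.25, 8.16 and 11.62, and pck1 had 5.52, 5.54, 7.49, 5.80 and 10.03. With the mix their differences from DMSO were 4.49, 4.38 and 4.51, and that of cyp1a was 2.098. The 3 genes are among the largest members of their lists there. The medians of these lists, 2.53 (glucocorticoid) and 1.84 (fasting), lay near the 2.22 of the centre of 11 body tissue lists. The 3 values thus do not show a response beyond the general rise of body tissue genes. Between toluene and benzene, igfbp1a, which is induced in the fasted liver, went the other way. It had levels of 8.73 with DMSO, 9.62 with benzene, 7.98 with toluene, 9.55 with formaldehyde and 13.05 with the mix.

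Of the probe sets past the filter, 27 were at least 2-fold higher and 24 at least 2-fold lower with all 3 single compounds, each against the same DMSO array. Higher were the Hsp110 family gene hspa4a (1.77 with benzene, 1.76 with toluene, 1.99 with formaldehyde and 1.66 with the mix), the ferritin gene fthl28 (1.32, 1.26, 1.24 and 3.46), anxa5b (1.17, 1.46, 1.15 and 1.02) and aco1, an iron-regulated aconitase (1.06, 1.31, 1.55 and 2.76). Lower were psap (-1.48, -1.56, -1.32 and -1.50), irg1l (-1.03, -1.71 and -2.10, and 1.82 with the mix) and mhc1ufa. The pyrimidine synthesis gene cad was among them on 1 probe set (-1.46, -1.84, -2.23 and -1.72), while its probe set of higher level gave 0.06, 0.01, -0.11 and -0.67. The alcohol dehydrogenase adh8b had 0.98, 1.11, 1.35 and 2.28. With the mix, 15 of the 27 higher probe sets were also at least 2-fold higher. Of the 24 lower ones, 16 were also at least 2-fold lower with the mix. Among the 4 arrays without the mix, 51 probe sets set the DMSO array at least 2-fold apart from each of the others. The same count was 44 for benzene, 33 for toluene and 180 for formaldehyde. The 51 are the same probe sets as the 27 and 24 above, so this count is no separate check of the DMSO array. Since every single array set itself apart in this way, effects common to the 3 compounds cannot be told from a trait of the DMSO array.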
